A study of Homo sapiens with 5 samples.

How the data were processed

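The study treated HL-60 cells, an established human promyelocytic leukaemia cell line, with decitabine or with the solvent DMSO and measured translation by ribosome profiling. Ribosome profiling sequences the mRNA fragments that ribosomes protect from nuclease digestion, and comparison with total RNA of the same lysate gives the translation efficiency of each transcript. Decitabine, a deoxycytidine analogue that is incorporated into DNA and traps DNA methyltransferases, was added at the start and again after 24 and 48 hours, each time at 100 nM, and lysates were made at 72 hours, per the labels' protocols. The labels list 2 total RNA libraries of decitabine-treated cells, 2 of DMSO-treated cells and 1 pooled library of ribosome-protected fragments, whose samples carried barcoded linkers. The wells were seeded in duplicate, per the labels' protocols.

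Reads were processed with Bowtie2, SAMtools 1.11 and UMI-tools 1.1.1 against the human genome build hg38, per the submitters' processing notes, and the role and settings of each tool are not given in the sources used here. UMI-tools handles unique molecular identifiers. The deposited table holds 1 transcript for each of 6309 genes and 4 values per transcript, and none of its columns belongs to a single library. The first value is a model coefficient for the drug on a log scale. It was taken as a natural log, in the way R reports the coefficients of a generalised linear model, since the header of the deposited table carries R's names for such a coefficient and its z test, but the log base is not stated. If the coefficient were a log2 value, each fold given here would lie closer to 1. The remaining values are, per the file headers, the two-sided p-value of that coefficient, its adjusted p-value and a q-value. The deposited adjusted p-value equals the Benjamini-Hochberg adjustment of the p-value over all genes, with a largest difference of 6.61e-14, and the q-value is the adjusted p-value times 0.83 for every gene. The program that fitted the model, its count filter, the scaling of the libraries, and how replicates entered the model are not given in the sources used here. A positive coefficient was read as higher translation efficiency with drug, from the table's own description and the name of the coefficient.

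Read counts and values per library were not analysed here, so the depth of each library is unknown. The error of each value is an implied standard error, the coefficient divided by the z that its p-value corresponds to. It had a median of 0.25, with a 5th percentile of 0.11 and a 95th percentile of 0.45. It measures only what the authors' model counted as error. The wells were seeded in duplicate, but the sources used here do not say whether from separate starting cultures, so p-values measure at most the spread between these samples, which can be technical, and they can hold counting error alone. After centring on the median, z had an SD of 1.46 among the most precise 20% of genes and 1.06 among the least precise 20%, where unchanged genes with fully counted error give 1. No SD and no n stand beside the values for that reason.

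The planned test of counts could not be run on this table. Genes were called at an adjusted p-value below 0.05 in the deposited table and counted by direction. Before the data were examined, 38 gene lists were fixed, with markers of other blood lineages among them; 34 had at least 5 members in the table and were tested. Each list was tested against all other genes with cameraPR of limma 3.58.1 in R 4.3.3, on z with the sign of the coefficient, a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, two-sided. Such a test treats genes, which are not independent replicates, as its units. With no values per library the correlation between genes could not be estimated, so 0.05 and 0.1 were tried instead. Gene names were matched to RefSeq (GRCh38.p14) by symbol for 6124 genes and by an older symbol for 162, and 23 were left unmatched. The positions given are whole-gene spans from that annotation, on the chromosomes of the build that the submitters named.

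The genes named are, by a rule fixed in advance, the 15 with the smallest p-value among the calls in each direction, up to 4 members of each list with the smallest p-values, and 20 genes chosen beforehand; any other gene named was chosen after its values were seen. The alternatives were other thresholds and adjustments, a minimum size, centring of the coefficients on their median or precision-weighted mean, removal of imprecise transcripts, other gene statistics, larger correlations, and 10000 random lists of the same size, also matched in 20 bins of implied standard error. A filter on abundance could not be applied, because the table gives none.

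The procedure was tested on simulated data made from the implied standard errors of all 6309 genes, in 20 runs with 200 changed genes each. A false share of 4.3% of calls resulted. The simulated genes were independent and their errors were drawn from the same standard errors that the test used, so a share below the threshold was built in. It does not give the error rate of the deposited calls. Deposited z after centring had an SD of 1.46 among the most precise 20% of genes. Coefficients of 0.3 in either direction were recovered for 3.61% of the changed genes, and for 16.4% of those with implied standard errors in the lowest 20% of the table. For coefficients of 0.6 these shares were 24.9% and 80.2%. A list of large ribosomal subunit proteins shifted by -0.2 was found in all 20 runs. Every member was given the same shift and the genes were independent, so this does not give the chance of finding such a list in the deposited table. Of the calls in the deposited table, 44 were among those most precise 20% of genes.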

Results

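Translation efficiency, the amount of ribosome-protected mRNA relative to total mRNA, was compared between decitabine-treated and DMSO-treated HL-60 cells at 72 hours. Decitabine was dosed at 100 nM. The labels gave 2 total RNA libraries per treatment and 1 pooled library of ribosome-protected fragments. Results were available as 1 coefficient per gene for 6309 genes in the authors' deposited table, with no value per library, so all errors below are standard errors implied by the authors' p-values. The depth of the libraries is unknown.

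Few single genes differed in translation efficiency past the threshold between decitabine and DMSO. At an adjusted p below 0.05 in the authors' deposited table, 51 of 6309 genes changed, of which 40 were higher and 11 were lower with drug. The lower genes were led by components of the translation machinery and by ACTG1, encoding cytoplasmic gamma-actin. The higher genes were led by MPO, the myeloperoxidase of neutrophil granules, and by the chaperone genes HSP90AA1, CALR and HSPA8. Changes were small among the best-measured genes: the coefficient was 0.17 ± 0.02 (implied SE) for MPO and -0.23 ± 0.03 for EEF1A1 in the authors' deposited table, which on a natural log scale are 1.19 and 0.795 times the DMSO level. Without adjustment, 650 genes had a p below 0.05, against 315.5 that chance would give; 527 were higher and 123 lower, and after subtraction of the median of all coefficients 233 were higher and 268 lower.

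The split between higher and lower calls depended on where zero was placed. The median coefficient of all genes was 0.09 rather than 0 in the authors' deposited table, and 65% of coefficients were above 0. After subtraction of that median, 5 genes were higher and 32 were lower. All 11 lower calls passed again, and so did HSP90AA1, CALR, FTL, NCL and HSPA8, whereas the other higher calls no longer passed although all 40 lay above the median. The lower calls and these 5 genes are the ones that passed under both placements of zero, and no called gene changed sign.

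**Figure D1:**
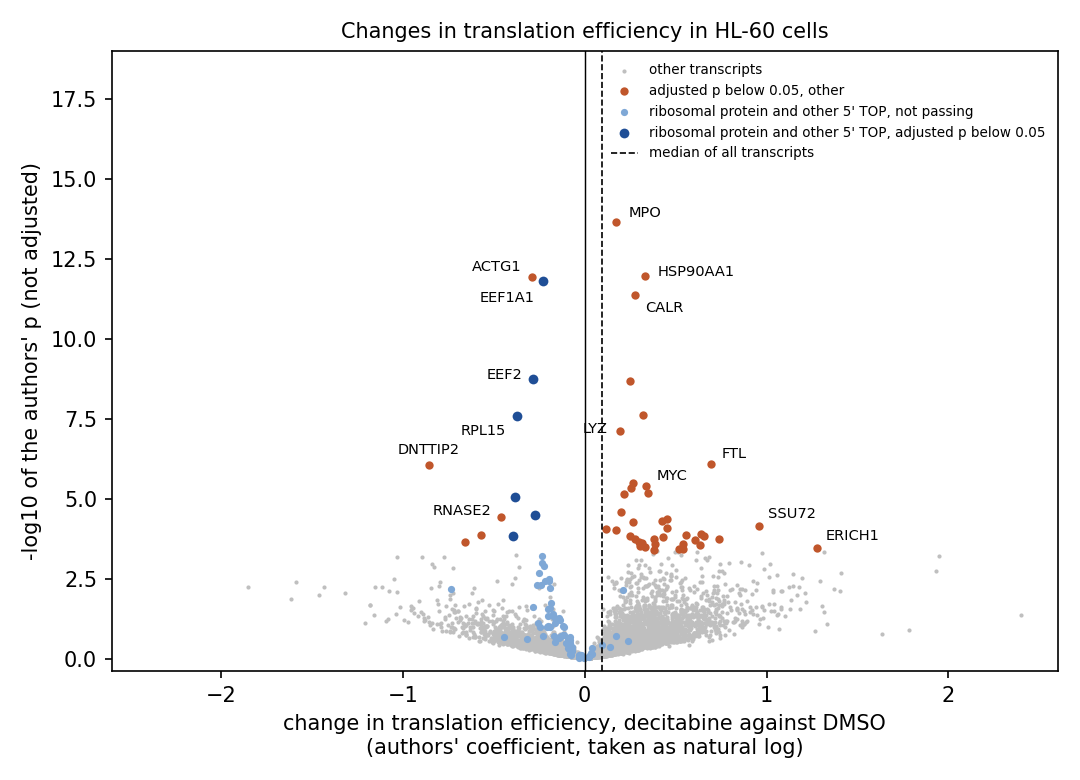
Change in translation efficiency with decitabine against DMSO (x axis, the authors' coefficient, taken as natural log) and minus log10 of the unadjusted p (y axis) for each gene except IL32, which lies off the scale. Blue points are ribosomal protein and other TOP mRNAs and lie mostly left of the dashed line, the median of all genes at 0.09; dark blue and orange points passed the adjusted threshold.

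Transcripts of ribosomal proteins lay below other genes as a group. Relative to the median of all genes, the median of the large subunit list was -0.23 and that of the small subunit list -0.23. Of 35 measured proteins of the large subunit, 33 had a coefficient below 0, and their median was -0.14 in the authors' deposited table. For 25 small subunit proteins the median was also -0.14, and 20 were below 0. Few members passed singly. RPL15 fell, with a coefficient of -0.37 ± 0.07 (implied SE, adjusted p = 1.79e-05), RPL10 fell with -0.38 ± 0.09 (adjusted p = 0.00308), and RPS3 fell with -0.27 ± 0.07 (adjusted p = 0.0104), all values from the authors' deposited table. No ribosomal protein gene was higher past the threshold; RPLP2 had a coefficient of 0.24 and an adjusted p of 0.768, and was looked at after its values were seen. Adjusted over the list alone, 8 large and 4 small subunit genes were lower and none was higher. After centring on the median of all genes, 7 and 4 members passed, all lower. The list test with cameraPR gave an adjusted p of 7.95e-18 for the large and 6.56e-10 for the small subunit. With an inter-gene correlation of 0.1 in place of 0.01 the values were adjusted p = 2.13e-05 and 0.000838.

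Other mRNAs that begin with a terminal oligopyrimidine (TOP) motif, the sequence that ribosomal protein mRNAs share at their start, were low as well. This list had 15 measured members, a median of -0.17 and 3 lower calls in the authors' deposited table: EEF1A1 and EEF2, which encode the elongation factors eEF1A and eEF2, and VIM, which encodes the intermediate filament protein vimentin. The coefficient of EEF2 was -0.28 ± 0.05 (implied SE, adjusted p = 1.88e-06) and that of VIM was -0.40 ± 0.10 (adjusted p = 0.0276) in the authors' deposited table. EEF1A1 had an adjusted p of 2.55e-09 there. Among the members that did not pass, EEF1G had -0.19 (adjusted p = 0.163). Adjusted over the list alone, 5 members were lower and 1 was higher. The cameraPR adjusted p of the list was 6.56e-10, and it was 0.377 when the coefficient itself, which weighs precise and imprecise genes alike, replaced z. The small subunit list then had an adjusted p of 0.156. With the extreme coefficient of IL32 also left out, a choice made after it was seen, these values were 0.119 and 0.0293. On z and without the 3 members that passed singly, the adjusted p of the other TOP list was 0.0152.

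Other groups of the protein synthesis machinery did not show this shift. The median coefficient in the authors' deposited table was 0.11 for 24 translation initiation factors outside the TOP list, 0.12 for 55 mitochondrial ribosomal proteins and 0.17 for 13 aminoacyl-tRNA synthetases. Of the initiation factors, EIF4G1, the scaffold of the cap-binding complex, rose with a coefficient of 0.28 ± 0.07 (implied SE, adjusted p = 0.0306) in the authors' deposited table, but not after centring (adjusted p = 0.45). None of the mitochondrial ribosomal proteins or synthetases passed. The cameraPR adjusted p was 0.404, 0.793 and 0.101 for these lists in the same order. The difference between the other TOP mRNAs and the initiation factors was -0.29 in medians (permutation test, 100000 permutations, two-sided p = 0.00077), in a test chosen after both medians were seen.

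**Figure D2:**
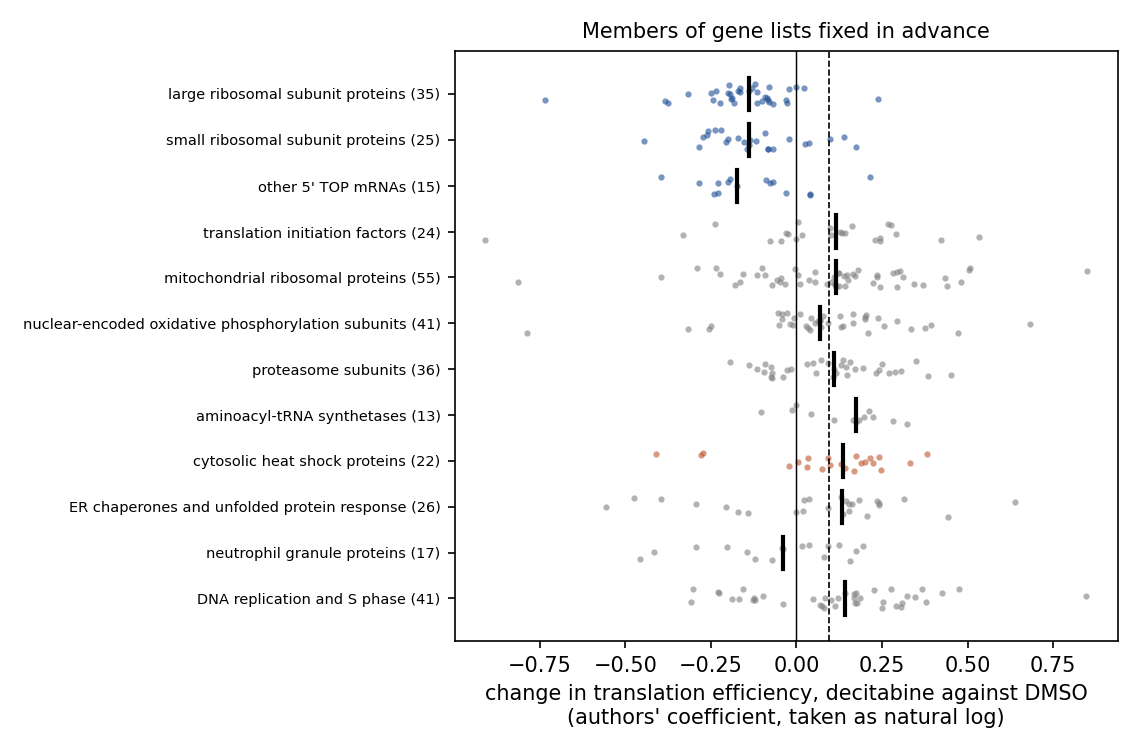
Coefficients (x axis, natural log assumed) of the members of 12 gene lists fixed before the data were examined, with the number of measured members in brackets; each point is a gene, thick bars are list medians and the dashed line is the median of all genes. Blue lists passed as lower and the orange list as higher in the list test on z, and grey lists did not pass.

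Cytosolic chaperones included 3 genes with higher translation efficiency among 22 measured. HSP90AA1, the inducible HSP90, rose with a coefficient of 0.33 ± 0.05 (implied SE, adjusted p = 2.45e-09), HSPA8, the constitutive HSC70, rose with 0.25 ± 0.04 (adjusted p = 1.89e-06), and HSP90AB1 rose with 0.21 ± 0.05 (adjusted p = 0.00262), in the authors' deposited table. The other 19 did not pass; HSPD1, a mitochondrial chaperone that the list also holds, had 0.17 (adjusted p = 0.169) in the authors' deposited table. Adjusted over the list alone, 5 were higher. The list as a whole passed (cameraPR adjusted p = 0.000189), but not without those 3 genes (adjusted p = 0.415), after centring on the median (adjusted p = 0.15), with a correlation of 0.1 (adjusted p = 0.0677), or on ranks of z (adjusted p = 0.107). Against 10000 random lists of the same size its median did not stand apart (adjusted p = 0.917). Its median of 0.14 lay 0.04 above that of all genes.

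Chaperones of the endoplasmic reticulum did not pass as a list of 26 (cameraPR adjusted p = 0.47). CALR, encoding the calcium-binding chaperone calreticulin and placed in the antigen presentation list, rose with 0.28 ± 0.04 (implied SE, adjusted p = 5.42e-09) in the authors' deposited table. DNAJB11, with 0.64 (adjusted p = 0.103), and PDIA6, with 0.24 (adjusted p = 0.122), did not pass there. Adjusted over the list alone, 5 of the 26 were higher.

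With zero placed as deposited, granule genes included calls in both directions. Of 17 measured genes of the neutrophil granule list in the authors' deposited table, MPO and LYZ, encoding lysozyme, were higher, RNASE2, encoding a ribonuclease of eosinophil granules, was lower and 14 did not pass. The list also holds RNASE3 and PRG2, which are likewise known chiefly from eosinophil granules. The coefficients were 0.19 ± 0.04 (implied SE, adjusted p = 4.82e-05) for LYZ and -0.46 ± 0.11 (adjusted p = 0.011) for RNASE2 in the authors' deposited table. MPO had an adjusted p of 1.36e-10 there and one of 0.0781 after centring on the median, but it passed after centring on the precision-weighted mean (adjusted p = 0.0387). LYZ passed after neither centring (adjusted p = 0.301 and 0.233, in that order), whereas RNASE2 passed after both (adjusted p = 0.000437 and 0.00056). The list did not pass on z (cameraPR adjusted p = 0.716) and was lower on z centred on the median (adjusted p = 0.0278), where RNASE2 and PRG2 were its lower calls, but not against random lists matched on implied standard error (adjusted p = 0.139). None of 24 monocyte and neutrophil differentiation markers passed. Markers of other lineages were nearly missing from the table, which held 3 of 30 erythroid and megakaryocyte genes and 1 of 29 lymphoid genes, too few to test. TFRC, the transferrin receptor, which is listed among both erythroid and iron genes, rose with 0.26 ± 0.06 (implied SE, adjusted p = 0.002) in the authors' deposited table.

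Further higher calls included FTL, MYC, MCM4 and NCL. FTL, the ferritin light chain, had 0.70 ± 0.14 (implied SE, adjusted p = 0.000457), about 2-fold on a natural log scale, in the authors' deposited table. MYC, the growth-promoting transcription factor, had 0.34 ± 0.07 (adjusted p = 0.00185), and MCM4, a subunit of the replicative helicase, had 0.35 ± 0.08 (adjusted p = 0.00262) in the authors' deposited table. NCL, encoding nucleolin, was higher by 0.32 ± 0.06 (adjusted p = 1.79e-05), and the RNA-binding proteins HNRNPU and KHSRP had 0.27 ± 0.06 (adjusted p = 0.00158) and 0.43 ± 0.11 (adjusted p = 0.0138) in that table. PRKDC, the catalytic subunit of DNA-dependent protein kinase, had 0.20 ± 0.05 (adjusted p = 0.00856), and TXNDC5, a protein disulphide isomerase, 0.45 ± 0.11 (adjusted p = 0.0127) in the authors' deposited table. FTL and NCL passed after centring; MYC (adjusted p = 0.121), MCM4 (adjusted p = 0.129) and TFRC (adjusted p = 0.231) did not. Neither the iron list (cameraPR adjusted p = 0.114) nor the list of 41 replication genes (adjusted p = 0.269) passed.

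Apart from the TOP genes, the lower calls were ACTG1, RNASE2, DNTTIP2, PFDN5 and ETFB. ACTG1 fell with -0.29 ± 0.04 (implied SE, adjusted p = 2.45e-09) in the authors' deposited table, while ACTB, encoding the closely similar beta-actin, had 0.12 ± 0.03 (adjusted p = 0.0202) and 0.918 as its adjusted p after centring. These actins are closely similar in sequence, and ribosomal protein genes and EEF1A1 have many processed pseudogenes. How reads shared by such copies were counted is not given in the sources used here, so these values are uncertain. Called genes outside the ribosomal protein and TOP lists were not checked for pseudogenes, so higher calls can share this uncertainty. DNTTIP2, a nucleolar protein, had the lowest coefficient of the calls, -0.86 ± 0.17 (adjusted p = 0.000457), in the authors' deposited table. PFDN5, a prefoldin subunit, had -0.57 ± 0.15 (adjusted p = 0.0276), and ETFB, a subunit of the mitochondrial electron transfer flavoprotein, had -0.66 ± 0.18 (adjusted p = 0.0343) there.

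Positions on hg38, as whole-gene spans, are given for several of the called genes. MPO lies on chromosome 17 from 58269855 to 58280935, HSP90AA1 on chromosome 14 from 102080742 to 102139749, and CALR on chromosome 19 from 12938609 to 12944489. EEF1A1 lies on chromosome 6 from 73515750 to 73521032, EEF2 on chromosome 19 from 3976056 to 3985463, and ACTG1 on chromosome 17 from 81509971 to 81512799. RPL15 lies on chromosome 3 from 23916545 to 23924631, and RPL10 on chromosome X from 154398065 to 154402339.

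Genes tied to the drug's target and to RNA modification did not pass, with the exceptions named here. Of 20 genes chosen beforehand, 12 were in the authors' deposited table, and only MYC and MPO passed. DNMT1, the maintenance DNA methyltransferase, had 0.08 (95% interval -0.10 to 0.25), and the m6A methyltransferase subunits METTL3 and METTL14 had 0.11 (-0.38 to 0.59) and 0.17 (-0.29 to 0.63) in the authors' deposited table. DCP2, the catalytic subunit of the mRNA decapping complex, had 0.55 (0.04 to 1.07) with an adjusted p of 0.429, and DCP1A had 0.14 (-0.35 to 0.64) in the same table. In the authors' deposited table the values were 0.10 (-0.18 to 0.38) for the m6A reader YTHDF2, -0.32 (-1.25 to 0.60) for cytidine deaminase (CDA), -0.11 (-0.44 to 0.22) for MCL1 and -0.08 (-0.75 to 0.58) for BCL2. ATF4, the main effector of the integrated stress response, had 0.20 (-0.29 to 0.70) there. These intervals use the implied standard errors, and each leaves room for changes as large as those of some called genes. DNMT3A, DNMT3B, UHRF1, DCK, SAMHD1, SLC29A1, DDIT3 and CDKN1A were not analysed here. In the DNA methylation list TET3 had 0.98 ± 0.28 (implied SE, adjusted p = 0.0535) in the authors' deposited table and none of 9 members passed, although 1 was higher when adjusted over the list alone. In the m6A list HNRNPA2B1 was higher, with 0.25 ± 0.07 (adjusted p = 0.0276) in the authors' deposited table and 0.466 as its adjusted p after centring.

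The remaining lists gave no call as a group. Altogether 30 of 34 lists did not pass with cameraPR, the lowest adjusted p among them being 0.101. None of 15 interferon-stimulated genes, 18 integrated stress response genes, 10 p53 target genes, 41 subunits of oxidative phosphorylation, 36 proteasome subunits or 32 mitosis genes passed singly in the authors' deposited table. Glycolysis had 2 higher calls among 16, LDHA with 0.26 and ENO1 with 0.17, histones had 1 among 40, HIST1H2AH with 0.33, and the nonsense-mediated decay list had 1 among 20, SMG1 with 0.43, all in the authors' deposited table. The adhesion and cytoskeleton list, with ACTG1 and ACTB among its 25 members, did not pass (adjusted p = 0.47) but was lower after centring (adjusted p = 0.00237), though not against random lists matched on implied standard error (adjusted p = 0.139). Without ACTG1 and ACTB, and with no centring, its adjusted p with cameraPR was 0.797. For 5 of the lists that did not pass, the sign of the test and that of the median relative to all genes differed. No cancer-testis antigen and no mitochondrially encoded mRNA was among the genes analysed.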

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

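The count of 51 changed genes became 19 at an adjusted p below 0.01, 86 below 0.1, 18 with the Benjamini-Yekutieli adjustment and 5 with a minimum log2 change of 1; the higher calls then numbered 13, 66, 12 and 4 and the lower calls 6, 20, 6 and 1, which follows from the thresholds. The counts at a minimum log2 change of 1 take the coefficient as a natural log; read as log2, ERICH1 (1.28 in the authors' deposited table) would be the only call to reach 1. The authors' q-value gave 60 and removal of the 25% of genes with the largest implied standard errors 58. Centring on the median gave 5 higher and 32 lower calls, and centring on the precision-weighted mean 6 and 31, against 40 and 11 as deposited, which follows from the shift of every coefficient; 16 of the 51 genes passed again after centring on the median, and no called gene changed sign. The 4 list calls fell to 1 when the coefficient replaced z, and to 2 when IL32 was also left out. The small subunit list thus failed only with IL32 included, and the cause of the remaining losses was not tested. The heat shock list turned lower in both of these runs (adjusted p = 0.991 and 0.993). The large subunit list passed in every alternative run, with adjusted p up to 0.0242; the small subunit list did so except on the coefficient (adjusted p = 0.156, and 0.0293 without IL32), and the other TOP list except on it with IL32 (adjusted p = 0.377) and without (adjusted p = 0.119). Centring of the list tests, centring on the precision-weighted mean and the standard error matched lists were chosen after the data were seen. So was the removal of IL32, of imprecise genes and of members that pass singly. Centring on the median was planned for the calls, for both their count and the single called genes. No paired analysis was possible because the table holds 1 coefficient per gene and no value per replicate; for the same reason leaving out a replicate, other count tests, RNA and footprint levels, and a filter on abundance were not run. Depth is unknown, and at the median implied standard error of 0.25 a coefficient of about 0.50 is needed for an unadjusted p of 0.05.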

Other observations

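Several further gene groups were looked at, some of which overlap the lists above. The tests in this part were chosen after the calls and list medians were seen, except the count of calls after subtraction of the median. The tests of pseudogenes, very long proteins and nucleolar factors were set down before their own values were known, and the rank correlation with pseudogene number was added after the first pseudogene result. After RNASE2 had been seen among the lower calls, other genes known chiefly from eosinophils were looked up, with no test of them as a group. The coefficients in the authors' deposited table were -0.38 for EPX (adjusted p = 0.0597, and 0.0053 after centring), -0.12 for PRG2 (adjusted p = 0.414, and 0.0274 after centring), -0.29 for RNASE3 (adjusted p = 0.845) and -0.08 for CLC (adjusted p = 0.933), so none of these passed as deposited. Of the azurophil granule genes that were looked up, ELANE with -0.20 and PRTN3 with -0.15 were below 0 in the authors' deposited table. CTSG with 0.02 and AZU1 with 0.09 were above 0. None of these passed, whereas MPO and LYZ were higher calls as deposited, though not after centring on the median. Further members of the neutrophil granule list were CTSD with -0.42, CEACAM8 with -0.07, SRGN with -0.04 and BPI with -0.04. CST7 with 0.04, CTSC with 0.08, SERPINB1 with 0.12 and DEFA3 with 0.16 were above 0, and none of these members passed in that table. Low values were thus not confined to eosinophil genes. CEBPE, a transcription factor of granulocyte differentiation, had -0.38 there (adjusted p = 0.153, and 0.0388 after centring). Genes were also grouped by the letters at the start of their symbols. Of 68 such families of at least 10 genes, 2 passed on centred z, RPL and RPS, and the lowest adjusted p of the others was 0.304. The RPL and RPS families largely repeat the ribosomal protein lists above, so they are no separate evidence. None of 23 chromosomes passed (lowest adjusted p = 0.947 with cameraPR). IL32 had a coefficient of 17.2 with an implied standard error of 1116, the form a coefficient takes when one group has no reads on one side.

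The 75 ribosomal protein and other TOP mRNAs lay 0.23 below the median of all genes (95% bootstrap interval of the shift -0.28 to -0.20). No value per library was available, so the intervals here measure the spread between genes, not that between wells or libraries. No list among 10000 random ones matched on implied standard error had a median as low (share 1e-04, the smallest that can be given). A small error alone therefore does not account for the shift. That error is only a stand-in for abundance, which is not known here, so high abundance stays open. Subunits of oxidative phosphorylation, mostly short proteins, lay only -0.0247 from the median of all genes (interval -0.06 to 0.04). This argues against a shift shared by all short coding sequences. It rests on that list alone and coding lengths were not used, so a part played by length stays open. Reads shared with processed pseudogenes stay open: across the 71 members with more than 2 annotated pseudogenes the rank correlation of their number with the coefficient was 0.0456 (interval -0.19 to 0.28), and the other 4, with a median as low in a share of 3e-04 of matched lists, are too few to decide, since EEF2, VIM, EIF2S3 and EIF3A include no ribosomal protein, 2 of them are single calls and EIF3A had 0.21 in the authors' deposited table. The other TOP mRNAs lay below the initiation factors outside the TOP list, both lists taken from general knowledge with no motif searched for (permutation p = 0.00077), a test that largely restates the medians it was chosen from, so it remains a hypothesis that translation of TOP mRNAs as a class may be lower after decitabine; library preparation, slower growth and the drug itself were not separated by this design.

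The excess of higher calls may reflect the zero point of the coefficients. After subtraction of the median there were 5 higher calls against 32 lower ones, but subtraction lowers the higher calls whatever the cause, so this decides nothing. Sequencing libraries carry no absolute scale without an added standard, and none is named in the sources used here, so a general rise in translation efficiency and a scaling offset both stay open.

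The called genes DYNC1H1, LYST, SMG1, PRKDC, DMXL2 and CHD8 encode very long proteins. A list of 78 genes for very long proteins, written from general knowledge after the calls were seen, had 63 measured members. Its 6 called members, all higher, prompted the list, so their calls are no evidence for the class. None of these 6 passed after centring on the median (lowest adjusted p = 0.129). The 57 others had a median of 0.17, above 99.7% of matched random lists, which had a typical median of 0.10. Translation efficiency may thus be higher for very long coding sequences as a class, or footprints and RNA reads may have been recovered differently along long transcripts; coding lengths were not used here, and the genomic span of a gene, a poor stand-in, had a rank correlation of only 0.05 with the coefficient across 6286 genes, which are not independent replicates. A similar idea for nucleolar ribosome biogenesis factors, prompted by NCL, NOLC1 and EBNA1BP2, stays open: 74 measured genes of a list that left those out had a median of 0.07, above 12.2% of matched random lists and within their spread, and DNTTIP2, a nucleolar protein outside that list, was called lower.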
